A study of Homo sapiens with 6 samples.

How the data were processed

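The study measured binding of the transcription factor GATA3 by chromatin immunoprecipitation followed by sequencing (ChIP-seq) in MCF-7 cells. The labels give 3 treatments (DMSO, GDC-9545 at 300 nM and GNE-858 at 300 nM), each for 24 h, with 2 libraries per treatment. Libraries were grouped by the treatment in their titles and numbered as the titles number them. The labels do not say whether the 2 libraries of a treatment came from separate cultures, so the spread between them may be technical. The p-values for peak numbers and library similarity measure only that spread. Those for gene lists and location classes come from draws of genes or sites and do not measure the spread between libraries.

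Each library had 1 peak list in narrowPeak layout. Per the submitters' processing notes, the alignment and peak-calling tools named are GSNAP (version not given in the sources used here) and MACS2 version 2.1.0, and the genome build is GRCh38. Per the labels, Drosophila chromatin was added to the ChIP reactions as a spike-in and genomic input DNA was prepared. Whether either entered the peak lists is not given in the sources used here. The deposited lists carry a fold enrichment at the summit, which is a linear ratio for that peak within its own library. They also carry deposited −log10 p and −log10 q values for each peak. The deposited score was a whole number within 1 of 10 times the −log10 p, limited to 1000, and was not used. In each deposited list every −log10 p was above 2, that is, p was below 0.01. All of these values are the authors' own per-peak values, and they were used only to filter and rank peaks within a list. The lists hold no read counts, so the sequencing depth of the libraries is unknown here and no counting interval was computed.

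Peaks with a MACS2 q-value of 0.01 or lower were merged over all 6 libraries where they overlapped by at least 1 bp, and each merged interval was called a site. A site was present in a library if a peak at that q overlapped it, and absent if no peak overlapped it even in the list as deposited. A site between these states in either library entered no set. Lost sites were present in both DMSO libraries and absent from both libraries of a compound, and gained sites were the converse. GDC-9545-only and GNE-858-only sites were present in both libraries of the named compound and absent from both of the other. These 6 sets come from overlaps of lists with no test per site, so lost and gained refer to the lists. Each count was set beside the counts from the other 2 ways of dividing the same 4 libraries into pairs. The strength of a site was the percentile of its −log10 p within the library's own list, averaged over the 2 libraries that define the set. Sites of strength percentile 80 or more are called strong. That limit was chosen after the strength of the changed sites had been seen. Equal lists of the 20000 peaks with the highest −log10 p per library were used as an alternative, with absence still judged on the full lists.

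No genome sequence was used here, so the motif tests in the design were not run. Genes came from a RefSeq table for GRCh38.p14 that holds gene intervals without strand or exons. Each site was therefore assigned by its midpoint to the nearest protein-coding gene interval within 100 kb, and not to a transcription start as designed. Ties went to the shortest gene. Distances are from the site midpoint to the gene interval, and sites described as inside a gene could not be placed in exons or introns. For the same reason the location classes were inside a gene, within 1 kb of either end of a gene, and outside genes with none within 100 kb. Of the 326 symbols in the gene lists, 325 matched the table.

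Library similarity was the Jaccard index (shared sites over the union) for each pair of libraries, with an exact one-sided permutation over the 15 ways of pairing 6 libraries. Numbers of peaks were compared with exact two-sided permutation tests, whose p cannot go below 0.333 with 2 against 2. The 9 gene lists were estrogen response, luminal lineage, basal and mesenchymal, cell cycle, AP-1 and immediate early, interferon response, sterol and fatty acid synthesis, histone acetylation and readers, and blood and stromal cells. For each list and set, the list genes with a changed site were counted among list genes with any site. The count was compared with 100000 draws of genes matched on their number of sites (1, 2, 3 to 4, 5 to 8, and 9 or more), two-sided. The last group was open, so differences in site number within it were not matched. Location classes were compared with 100000 draws of retained sites matched on strength in 10 bins. Benjamini-Hochberg adjustment was applied within a set, over 9 lists or 3 classes. After the data had been seen, the test within 1 kb of gene ends was repeated for the 12 mixed pairs of libraries, adjusted over the 12. Sites and genes are not replicates, so these tests describe the 6 libraries. The overlap of the lost or gained sets was set beside 100 simulations in which treatments did nothing and shared the DMSO libraries, and beside 100 permutations of the library states within each site.

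Named genes were taken by rule. They were the genes of the 12 strongest changed sites of each set (1 site per gene), 15 fixed genes, up to 4 genes of any list that passed its test, and the genes nearest to the 5 strongest peaks of each library. The groups, tests, gene lists, naming rule and most alternatives were fixed before the data were examined. The alternatives were other peak thresholds, equal lists, a looser rule for absence, 50% or summit overlap, each library left out in turn, all genes within 50 kb, 2 kb around gene ends, and no matching on strength. A further 9 alternatives were added after the data had been seen, most of them restricted to strong sites or leaving out single libraries in the list and location tests. One of them matched genes on their number of strong sites held by both libraries of a set, since matching on sites of every strength ignores that some lists are rich in strong sites. On simulated lists placed at the positions of DMSO replicate 1, with some peaks missed at random, 164 of 200 planted lost sites were recovered, against 162 expected. A further 1158 sites that were not planted were also called lost, against 1131.5 expected from the random misses. Most sites called lost in that simulation were therefore not planted. The gene list test was checked apart from these, on simulated genes without peaks or sites. There 4% of 200 null gene lists had permutation p under 0.05, and 85% of 100 lists with planted signal were recovered. That check does not cover how sites were called or assigned to genes. The work used Python 3.11.15, numpy 2.4.6, pandas 2.3.3, scipy 1.17.1 and matplotlib 3.10.9.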

Results

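GATA3 binding was mapped by ChIP-seq in MCF-7, an estrogen receptor-positive breast adenocarcinoma line. GATA3 is a zinc-finger transcription factor of luminal breast cells. Cells were treated for 24 h with DMSO as vehicle, with 300 nM GDC-9545 (giredestrant, an estrogen receptor antagonist and degrader) or with 300 nM GNE-858, a compound known here by its code name, for which the labels give no target. Each treatment had 2 libraries, and each library had 1 peak list. At q of 0.01 or lower the lists held 139894 and 150615 peaks in DMSO, 141675 and 156460 peaks in GDC-9545, and 154096 and 139578 peaks in GNE-858. The lists carry no read totals, so depth is unknown. Coordinates are on GRCh38, and folds, −log10 p and ranks are the authors' per-peak values within 1 list.

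The strongest GATA3 peaks recurred across treatments. A peak inside CCDC47 on chromosome 17 (63752579 to 63753202 in DMSO replicate 1) was among the 5 strongest in all 6 libraries, with a fold of 19.2 in DMSO replicate 1 and 17.8 in DMSO replicate 2. Peaks near CRNN on chromosome 1 and inside CAMK1D on chromosome 10 also ranked among the 5 strongest in at least 1 library of each treatment. Merging gave 234652 sites with a median width of 435 bp, of which 83784 (35.7%) were present in all 6 libraries and 66729 (28.4%) in 1 library. A protein-coding gene lay within 100 kb of 81.0% of sites, and 50.2% of sites were inside a gene. All 15 genes fixed for description had at least 1 site present in every library. ESR1, which encodes estrogen receptor alpha, had 90 sites, 36 of them in all 6 libraries. GATA3 itself had 32 sites with 16 in all 6, and the estrogen-responsive gene GREB1 had 35 with 13 in all 6. TFF1 (4 sites), the pioneer factor gene FOXA1 (4 sites) and MYB (23 sites) had no site in any changed set.

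Neither compound moved the number of peaks beyond the spread between libraries. At q of 0.01 or lower the mean was 145254.5 ± 7581 (SD, n = 2) in DMSO, 149067.5 ± 10455 in GDC-9545 and 146837 ± 10266 in GNE-858. The ratio to DMSO was 1.03 for GDC-9545 (exact permutation p = 0.667; 0.958 in the lists as deposited) and 1.01 for GNE-858 (exact permutation p = 1), in a design that cannot go below 0.333. Libraries of 1 treatment shared slightly more sites (mean Jaccard index 0.642) than libraries of different treatments (0.630). The difference of 0.0123 had an exact one-sided permutation p of 0.0667, the smallest that 15 pairings allow, and without GDC-9545 replicate 1 it was −0.00241 and without GDC-9545 replicate 2 it was −0.000421. In equal lists of 20000 peaks the difference was 0.0550 (0.759 against 0.704), with the same p, and at −log10 q of 5 or more it was 0.01496 with an exact permutation p of 0.2. DMSO replicate 1 stood apart, with a mean index of 0.594 with the other 5 libraries against 0.634 to 0.647 for each of the others. It also had the largest share of peaks within 1 kb of a gene end, 11.3% against 9.34% to 10.4%.

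The comparison of GDC-9545 with DMSO asked where GATA3 binding differed when the estrogen receptor was targeted. Strong sites were almost all on the lost side, with 26 lost against 1 gained, while 30983 strong sites were present in both DMSO libraries. The strongest lost site with a protein-coding gene within 100 kb lay inside CUX1, a homeodomain transcription factor gene (chromosome 7, 101972817 to 101973474). Its peak ranked at percentiles 93.5 and 90.5 of the DMSO lists, and no peak overlapped it in either GDC-9545 list. The other named lost sites were near YIPF5, RIMS4, MPST, ARID1B (a SWI/SNF chromatin remodelling subunit), NR5A2 (the nuclear receptor LRH-1), RBM20, THADA, MAPKAP1, SCOC, CD276 (the immune checkpoint protein B7-H3) and TPM3. The 12 had strengths from 82.1 to 92.0, and 10 were inside a gene. The site near NR5A2 (chromosome 1, 200016726 to 200017330) was 10682 bp from the gene and ranked at 88.1 and 84.5 in DMSO. At the strong gained site, inside the DNA repair gene RAD51 (chromosome 15, 40714231 to 40714812), the 2 GDC-9545 libraries had percentiles of 83.3 and 85.1. Other named gained sites were weaker, from 72.7 to 78.8, and lay near FBXL20, TECPR2, GREB1, CARTPT, NMBR, SLC9A8, HCCS, ENAH, FRRS1, SIK3 and CNBD1. The GREB1 site (chromosome 2, 11568853 to 11569492) was inside the gene and was gained under both compounds. No strong site appeared in either other division of the same 4 libraries. The direction at strong sites depended on DMSO replicate 2, without which 36 were lost and 112 gained, while without DMSO replicate 1 the counts were 35 and 6. Without GDC-9545 replicate 1 they were 52 and 4, and without GDC-9545 replicate 2 they were 53 and 4.

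Over sites of every strength, 3950 sites (3.77% of those in both DMSO libraries) were lost and 5666 (4.86% of those in both GDC-9545 libraries) were gained under GDC-9545. Their median strengths were low, 35.8 and 30.7. The total of 9616 compares with 6644 and 5927 for the other divisions of these libraries. The gained-to-lost ratio of 1.43 turned to 0.554 without DMSO replicate 1 and 0.817 without DMSO replicate 2. It was 3.04 without GDC-9545 replicate 1, and at strong sites it was 0.0385. With any 1 library left out, lost sites numbered 6840 to 21033 and gained sites 10254 to 20772, since 1 library then decided presence or absence in its group.

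Estrogen response genes were over-represented among genes with a site lost under GDC-9545. Of 51 such genes with any site, 23 had a lost site against 11.9 expected (95% of draws 6 to 18; permutation p = 0.0005, adjusted p = 0.0045). PGR, which encodes the progesterone receptor, lost a site inside the gene (chromosome 11, 101033810 to 101034611) that ranked at 81.1 and 78.7 in the DMSO lists. Other examples were the site 8735 bp from CTSD (cathepsin D; chromosome 11, 1772407 to 1772916; strength 80.9), a site inside the LIM-domain gene FHL2 (DMSO percentiles 76.4 and 83.5) and a site assigned to PDZK1 (66.3), a gene in a region with near-identical copies. The ratio of 1.93 fell to 1.18 without DMSO replicate 1 (adjusted permutation p = 0.36) and to 1.11 without DMSO replicate 2 (adjusted permutation p = 0.421), where presence in DMSO rested on 1 library. Strong sites and equal lists were too few to test this list, with 1 gene against 0.179 expected at strong sites (genes matched on strong sites) and 0 genes against 0.0171 in equal lists, which held 4 lost sites in all. None of the other lists passed. Counts against expectation were 12 and 6.97 for AP-1 and immediate early genes (adjusted permutation p = 0.138), 10 and 7.89 for luminal lineage, 10 and 6.93 for basal and mesenchymal, 4 and 5.76 for cell cycle, 1 and 2.75 for interferon response, 6 and 5.09 for sterol and fatty acid synthesis, 8 and 6.27 for histone acetylation and readers, and 6 and 4.14 for blood and stromal cells. Among gained sites no list passed, and estrogen response had 13 genes against 14.7 expected (adjusted permutation p = 0.76).

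**Figure D1:**
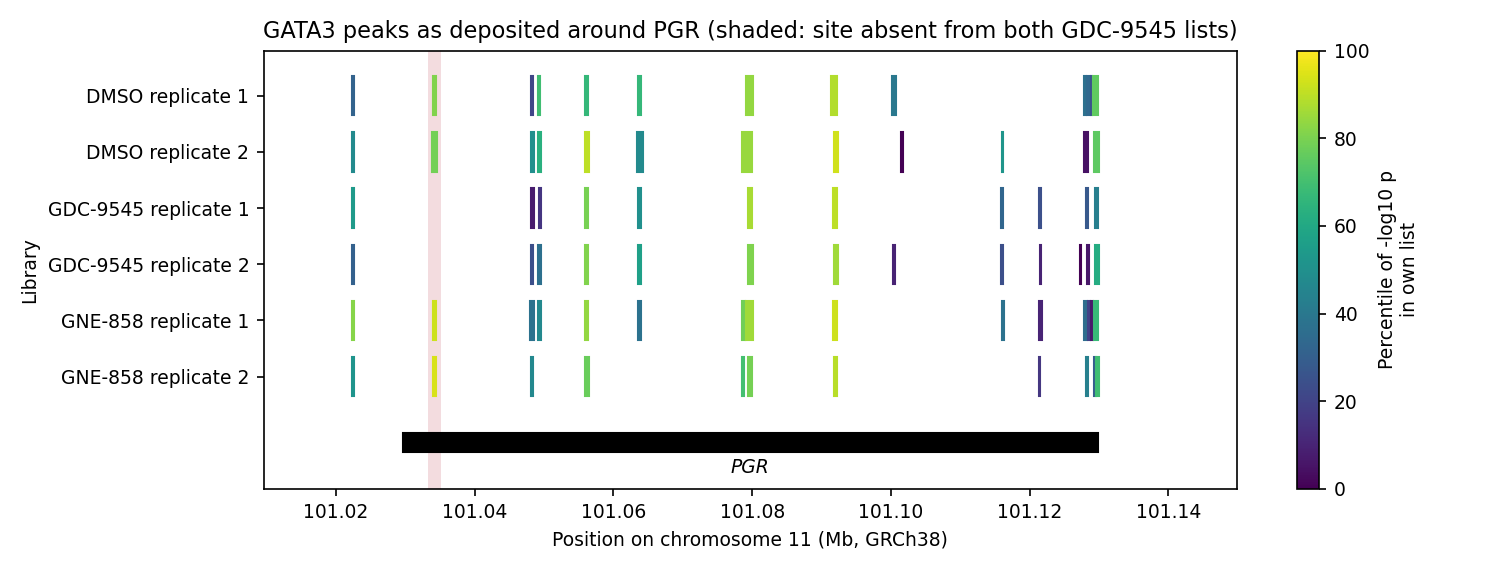
Peaks of the 6 deposited lists around PGR on chromosome 11 (x axis, position in Mb; y axis, library), coloured by the percentile of −log10 p in each library's own list, with the PGR gene as a black bar. The shaded site at 101033810 to 101034611 has a peak in both DMSO and both GNE-858 libraries and none in either GDC-9545 library.

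With all libraries kept, the comparison of GNE-858 with DMSO had the opposite balance at strong sites. There were 30 strong gained sites and 1 strong lost site, and all 30 were also absent from both GDC-9545 lists. The strongest was inside IGSF5, an immunoglobulin superfamily gene (chromosome 21, 39723327 to 39723983), at percentiles 96.6 and 96.7 of the GNE-858 lists. It was absent from the other 4 lists. The other named gained sites were near KCTD6, CPN2, GPAM (a mitochondrial glycerol-3-phosphate acyltransferase), LY86, SCOC, FABP6 (a bile acid-binding protein), MINDY4B, SETBP1, PRMT8, CFAP20DC and TSC22D3 (the glucocorticoid-induced leucine zipper). The 12 had strengths from 84.6 to 96.6, and 6 were inside a gene. Named lost sites were weaker, from 65.5 to 73.9. These were near GLRA2, GREB1, OR13H1, CFAP58, ITPK1, KIF1A, C3 (a complement component), LAMA3 (a laminin chain), PABIR2, IGFL2, KIF13B and IQSEC1. The lost GREB1 site (chromosome 2, 11535757 to 11536273) was inside the gene at percentiles 69.7 and 75.1 in DMSO. Other divisions of these 4 libraries gave totals of 0 and 1 strong sites against 31. The strong gained count was 120 without DMSO replicate 2, 51 without DMSO replicate 1 and 51 without GNE-858 replicate 2. The strong lost count stayed between 1 and 4 with any library left out. Without DMSO replicate 2, strong gained sites outnumbered strong lost ones under GDC-9545 too (112 against 36). The opposite balance of the compounds therefore depended on that library.

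Over sites of every strength, 2813 sites (2.69% of those in both DMSO libraries) were lost and 4391 (3.89% of those in both GNE-858 libraries) were gained under GNE-858. Their median strengths were 33.8 and 33.2. The total of 7204 was not above every other division, since DMSO replicate 1 with GNE-858 replicate 2 against the rest gave 7225 and the remaining division 5781. These totals therefore did not separate the treatment from differences between libraries. The gained-to-lost ratio was 1.56, and it turned to 0.514 without DMSO replicate 1 and 0.746 without DMSO replicate 2. Without GNE-858 replicate 2 it was 3.58. Lost sites numbered 5349 to 18759 and gained sites 8780 to 19142 with any 1 library left out. No gene list passed in either direction. Estrogen response genes with a lost site numbered 11 against 9.24 expected (adjusted permutation p = 0.818), and those with a gained site 17 against 12.5 (adjusted permutation p = 0.597). AP-1 and immediate early genes with a lost site numbered 10 against 5.36 (adjusted permutation p = 0.276).

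**Figure D2:**
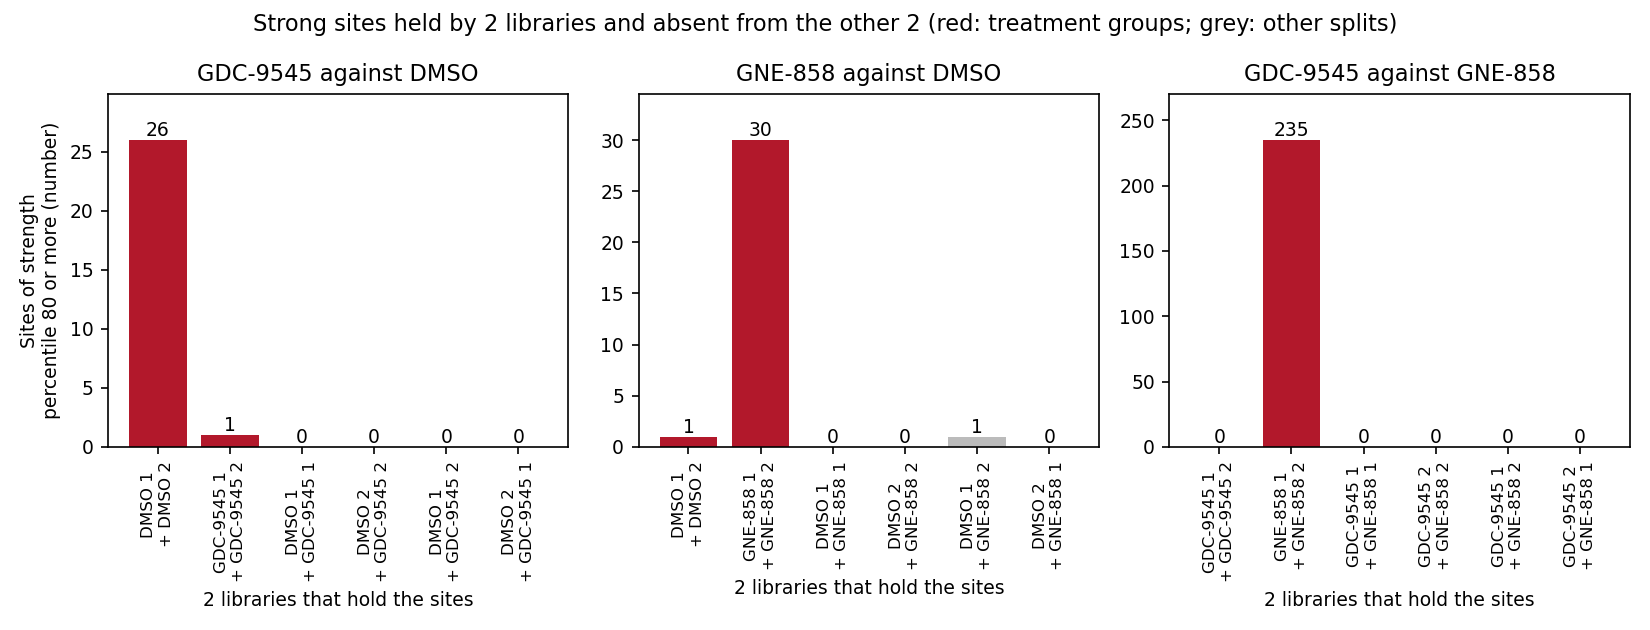
Number of strong sites (y axis) held by a pair of libraries and absent from the other pair, for each comparison, with treatment pairs in red and other divisions of the same libraries in grey. Treatment pairs gave 26 and 1, 1 and 30, and 0 and 235 sites, while the other divisions gave at most 1.

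The direct comparison of the compounds, at the same dose and time, was one-sided at strong sites. There were 235 strong GNE-858-only sites, 0.738% of the 31837 strong sites in both GNE-858 libraries, and 0 strong GDC-9545-only sites. Of the 235, 157 were present in both DMSO libraries and 30 were absent from both. The strongest was the site near NR5A2, at percentiles 99.1 and 99.1 of the GNE-858 lists, where the folds were 15.4 and 15.9. The site inside CD276 (chromosome 15, 73709891 to 73710619) was at 97.4 and 98.2. Sites near SPINK4, IGSF5, VPS37A, CUX1, RIMS4, ERN1 (the unfolded protein response sensor IRE1), RBM20, AMBP, MBOAT1 and LRP1B followed, with strengths from 94.8 to 96.8. Named GDC-9545-only sites were weaker, from 62.7 to 73.4, near SPMIP4, ATL1, DLD, BSPRY, EIF4E3, LAMA3, PSMA1, MEGF9, PRP4K, TMED2, SGPL1 and MCU. The other divisions of these 4 libraries gave 0 strong sites each. With any 1 library left out, the strong GNE-858-only count was 232 to 324 and the strong GDC-9545-only count 0 to 2. In equal lists of 20000 peaks there were 82 GNE-858-only sites and 0 GDC-9545-only sites, against 0 in both other divisions.

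**Figure D3:**
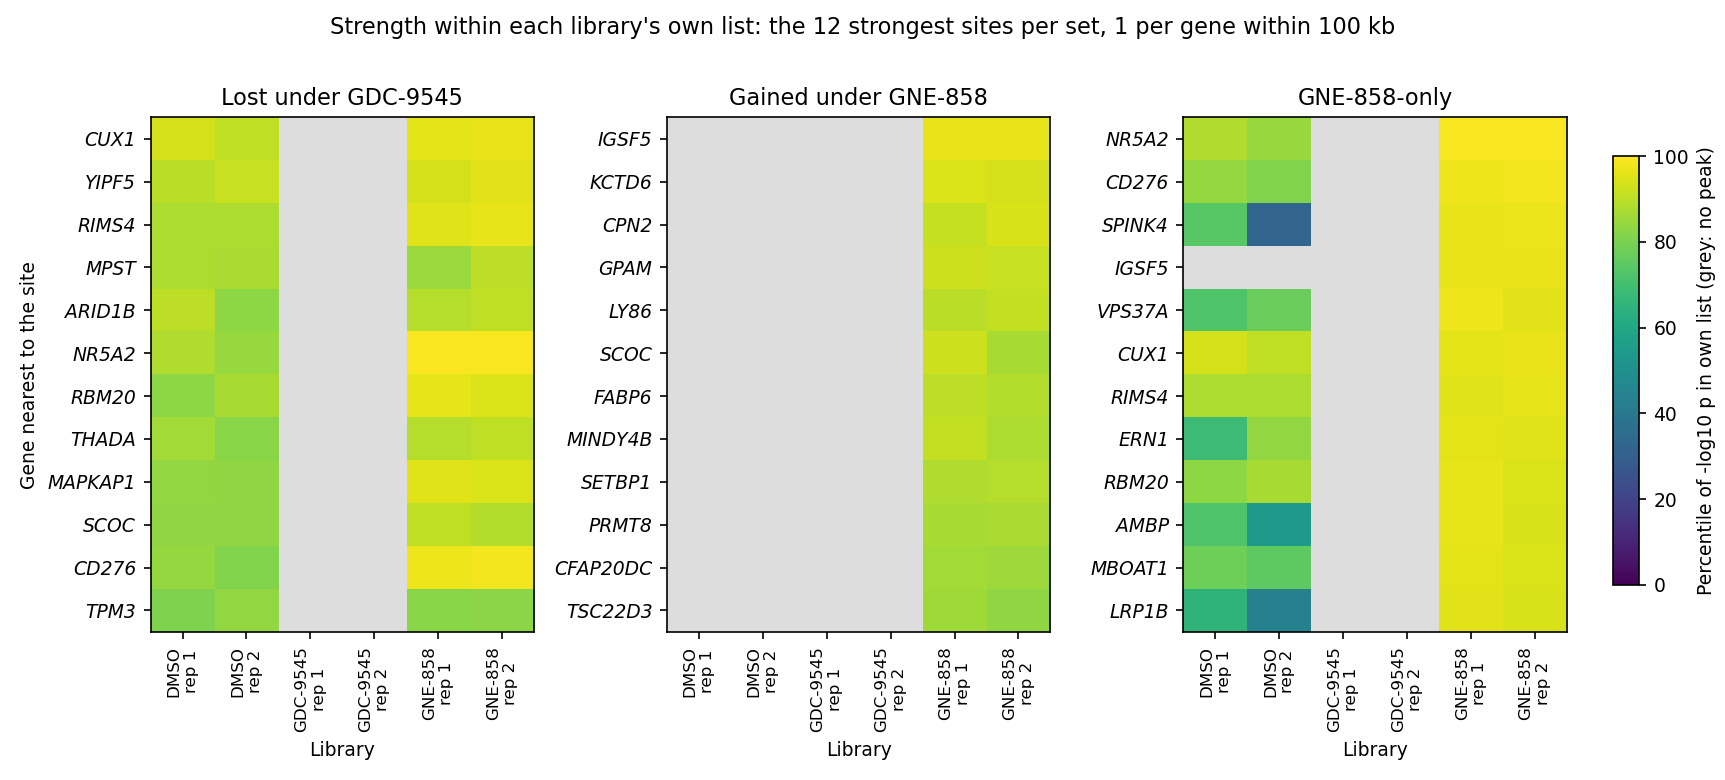
Percentile of −log10 p in each library's own list (colour; grey, no peak) for the 12 strongest named sites (y axis, nearest gene) lost under GDC-9545, gained under GNE-858 and GNE-858-only, in the 6 libraries (x axis). The sites lost under GDC-9545 have peaks in both GNE-858 lists, and the gained sites have none in the other 4 lists.

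Over sites of every strength, 4044 sites were GDC-9545-only and 4473 were GNE-858-only, with median strengths of 28.0 and 34.8. Their total of 8517 compares with 5504 and 6446 for the other divisions. With any 1 library left out the counts were 7362 to 18502 and 7788 to 18832. With absence judged at q of 0.01 they were 5869 and 5446, so which compound had more depended on the rule for absence. Estrogen response genes carried GNE-858-only sites more often than matched genes, 22 of 51 against 13.03 expected (95% of draws 7 to 19; adjusted permutation p = 0.0376). The strongest were the PGR site lost under GDC-9545, at percentiles 92.5 and 93.8 of the GNE-858 lists, a site 22579 bp from the secreted glycoprotein gene STC2 (strength 88.7), the FHL2 site (88.0), and a site inside NRIP1, a nuclear receptor corepressor gene (chromosome 21, 15005320 to 15005718). The NRIP1 site ranked at 88.1 and 83.6 in GNE-858 and at 17.1 and 12.2 in DMSO. At strong sites 6 estrogen response genes (PGR, STC2, FHL2, NRIP1, KRT13 and TGM2) compared with 1.65 expected from genes matched on their number of strong sites (95% of draws 0 to 4; permutation p = 0.00511, adjusted p = 0.046). Matching on sites of every strength gave 0.886 expected, which leaves out that these genes carry many strong sites. The PGR, STC2, FHL2, NRIP1 and KRT13 sites were also among the sites lost under GDC-9545. Both estrogen response results thus rest on absence from the same GDC-9545 lists and are not independent. Over all sites the ratio of 1.69 fell to 0.987 without GNE-858 replicate 1 (adjusted permutation p = 1), 1.18 without GNE-858 replicate 2 (adjusted permutation p = 0.234) and 1.37 without GDC-9545 replicate 1 (adjusted permutation p = 0.159). In equal lists it was 1.59, on 1 gene against 0.631 expected among 82 sites, too few to test.

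Basal and mesenchymal genes, and interferon response genes, also passed among GNE-858-only sites of every strength. For basal and mesenchymal genes the count was 14 of 33 against 7.53 expected (adjusted permutation p = 0.0376), with sites near VIM (vimentin; strength 70.4), SOX9 (64.9), ACTA2 (50.5) and ITGA6 (50.3). The ratio of 1.86 fell to 1.28 without GNE-858 replicate 1 (adjusted permutation p = 0.338), 1.32 without GNE-858 replicate 2 (adjusted permutation p = 0.0783) and 1.34 without GDC-9545 replicate 2 (adjusted permutation p = 0.155). For interferon response genes the count was 7 of 32 against 2.83 (adjusted permutation p = 0.0437), with sites near IRF2 (51.6), GBP1 (38.0), IFIT3 (33.3) and STAT1 (31.4). The ratio of 2.48 fell to 1.09 without GNE-858 replicate 1 (adjusted permutation p = 0.912), 1.04 without GNE-858 replicate 2 (adjusted permutation p = 1), 1.51 without GDC-9545 replicate 1 (adjusted permutation p = 0.349), 1.47 without GDC-9545 replicate 2 (adjusted permutation p = 0.325) and 1.45 when all genes within 50 kb were counted (adjusted permutation p = 0.276). No list passed among GDC-9545-only sites, where luminal lineage had 14 of 35 genes against 7.90 expected (adjusted permutation p = 0.127).

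The compounds shared lost and gained sites, and whether more than expected depended on the expectation. At strong sites 25 of the 26 sites lost under GDC-9545 were present in both GNE-858 libraries. Over all strengths 1169 sites were lost under both compounds, against 106 for independent lists. Because both comparisons use the same DMSO libraries, simulated treatments with no effect already shared 483 ± 18 lost sites (SD, 100 simulations). Permuting library states within sites gave 1121 ± 32, and the simulated and permuted sets held 3288 and 3475 sites on average. Carried to the observed 3950 and 2813 lost sites, the permutations give 1075 if overlap grows with the mean size. They give 1031 if it grows with the product of the sizes, and the observed 1169 was above both. The shared gained sites numbered 1343, against 529 ± 26 in the simulations and 740 ± 26 in the permutations. The simulated gained sets held 5134 sites on average, but the permuted ones held 3462, against 5666 and 4391 observed. Carried to the observed sizes, the permutations give 1067 shared gained sites if overlap grows with the mean size and 1537 if it grows with the product of the sizes, so they do not settle whether the gained overlap is in excess. Without DMSO replicate 1 the overlaps were 10865 lost and 3357 gained, and without DMSO replicate 2 they were 13983 and 7573. Setting each compound against its own DMSO library finds the same 1169 and 1343 sites by definition, and leaves no shared control in the expectation. Independent lists over all sites would then share 1532 or 1479 lost sites and 643 or 611 gained sites, depending on which DMSO library went with which compound. The lost overlap was below that expectation and the gained overlap above it, but this expectation treats all sites as equally likely to change. It also counts sites present in only 1 DMSO library, which cannot be in both lost sets. These raise the lost expectation, so the lower observed value does not argue against an excess of shared lost sites.

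Gained and compound-only sites were less often near gene ends than matched retained sites, but so were sites of mixed pairs of libraries that did not include DMSO replicate 1. Among sites gained under GDC-9545, 2.19% were within 1 kb of a gene end against 9.09% of strength-matched retained sites, and 26.0% were outside genes with none within 100 kb against 17.2% (permutation p = 1e-05 for both, the smallest the draws can give). For sites gained under GNE-858 the share near gene ends was 3.01% against 9.01%, for GDC-9545-only sites 2.70% against 8.42%, and for GNE-858-only sites 4.40% against 8.50% (adjusted permutation p = 1.5e-05 for each). Lost sites differed less, with 6.15% against 7.16% under GDC-9545 (adjusted permutation p = 0.024) and 5.69% against 6.90% under GNE-858 (adjusted permutation p = 0.018). The GDC-9545 call for lost sites ended with a 2 kb limit and without GDC-9545 replicate 1. In other divisions of the DMSO and compound libraries, pairs with DMSO replicate 2 had 2.57% to 3.13% near gene ends against 9.10% to 10.4% of their own matched retained sites, while pairs with DMSO replicate 1 had more than expected, 7.79% to 10.7% against 6.11% to 6.56%. In other divisions of the GDC-9545 and GNE-858 libraries the shares were 3.85% to 5.28%, a range that includes the GNE-858-only share, against 7.43% to 8.43% expected. Each of these 12 mixed pairs differed from its expectation (adjusted permutation p of 0.00054 or lower). The share of sites gained under GDC-9545 and the GDC-9545-only share lay below those of the mixed pairs of the same libraries, and the shares gained under GNE-858 and GNE-858-only did not. These differences between pairs were not tested.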

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

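The tests of list sensitivity, of ChIP efficiency and of movement at the same sites were chosen after the result was seen, and the test of chromosome segments was set before its result was seen.

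At 56 sites the compounds lay on opposite sides of DMSO. These sites were in both DMSO lists and absent from both GDC-9545 lists, and they were in the top 20000 of both GNE-858 libraries but outside it in both DMSO libraries. The difference was not tested at the level of libraries.

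The wider pattern is the 82 sites that were in the top 20000 of both GNE-858 libraries and absent from both GDC-9545 lists. Shorter or less sensitive lists, if not confined to the GDC-9545 pair, would let other sets of libraries lack such sites too. Over the 84 combinations of 2 holding and 2 lacking libraries that did not lack both GDC-9545 libraries, the highest count was 15, against 82. That combination was again held by both GNE-858 libraries, and it lacked DMSO replicate 1 and GDC-9545 replicate 2. A lower sensitivity of the GDC-9545 pair alone would not raise these counts, so they cannot decide on it. Absence was judged on the lists as deposited, of which GDC-9545 replicate 1 was the shortest (155589 peaks) and GDC-9545 replicate 2 had 166165, against 156917 to 175703 in the other libraries. The highest count lacking both of the shortest lists, GDC-9545 replicate 1 and GNE-858 replicate 2, was 0. The 82 sites are held by GNE-858 replicate 2 and could not enter that count, which covers only sites of other libraries. Local copy-number loss would crowd the sites into few segments, but they fell in 76 different windows of 5 Mb, within the 70 to 79 of random draws. Lower ChIP efficiency in both GDC-9545 libraries would lower their folds at the 83784 sites present in all 6 libraries. Their median folds there were 6.65 and 6.75, the highest of all, against 5.98 to 6.44 in the other libraries. They also had the highest maximum −log10 p (334 and 357, against at most 332). Their mean number of peaks at −log10 q of 5 or more was the highest too (100122, against 95090 in GNE-858 and 88070.5 in DMSO). These values go against lower efficiency. They do not exclude it. The gap of 0.214 between the lower GDC-9545 median and the highest other median was within the largest difference between libraries of 1 treatment (0.456). GDC-9545 replicate 2 had the lowest maximum fold (26.7, against 29.1 to 30.5). GDC-9545 replicate 1 had 92104 peaks at −log10 q of 5 or more, fewer than GNE-858 replicate 1 (104165) and DMSO replicate 2 (93685). The lists also hold no read counts. A difference between the treatments in where GATA3 binds may account for the pattern and also stays open.

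Sites lost under GDC-9545 that both GNE-858 libraries held were also more often among the strongest peaks under GNE-858 than in DMSO. Of 1084 such sites, 62 were in the top 20000 of both GNE-858 libraries and 4 in that of both DMSO libraries, a ratio of 15.5. Retained sites matched on DMSO strength gave 7.47 and 3.67 on average, a ratio of 2.04, and their GNE-858 count ranged from 4 to 13 in 95% of draws (permutation p = 1e-05, the smallest the draws can give). A general shift of ranks in the GNE-858 lists is therefore too small to give the pattern. Opposite movement of GATA3 at the same sites is a candidate explanation, found and tested on the same lists, and the comparison of ranks between lists carries no test across libraries.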

How the results depend on the processing

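The settings restricted to strong sites, and the list and location tests with a library left out, were chosen after the data had been seen, as were the replicate block and the division of DMSO libraries between the comparisons. No paired analysis was possible for the site sets because presence in both libraries of 1 group and absence in both of the other is the same condition under either pairing of replicate numbers. For peak numbers, a replicate block gave mean ratios to DMSO of 1.03 for GDC-9545 (exact permutation p = 0.5, the smallest for 2 pairs) and 1.01 for GNE-858 (exact permutation p = 1). Same-numbered libraries of different groups were no more alike (Jaccard index 0.628) than others (0.631). The motif tests were not run, since no genome sequence was used. With 3 divisions of 4 libraries, the divisions are too few for a share under 0.05. Overlap by 50% or by summit left each count within 1.5 times its main value. Among the values that answer a comparison, 139 alternatives kept their direction and side or stayed near the main value, 7 reversed and 104 moved. Some of the 139 were fixed in advance, so the tally does not measure robustness. These include the overlaps with DMSO libraries divided, and strong-site list tests of sets without a strong site assigned to a gene. Counts over all sites rise when a library is left out by construction, since 1 library then decides presence or absence. For the other changes the cause was not tested, except that stricter thresholds and strong sites keep fewer sites. Read depth is unknown, so its limit on these lists is unknown.

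With lists as deposited, sites lost under GDC-9545 were 6346, lost under GNE-858 4987, gained under GNE-858 6802 and GNE-858-only 6831, and the overlaps of lost and gained sites were 2304 and 2086. At −log10 q of 5 or more, lost and gained sites were 436 and 941 under GDC-9545 and 149 and 627 under GNE-858, and compound-only sites were 397 (GDC-9545) and 1049 (GNE-858). The gained-to-lost ratios were then 2.16 and 4.21, the overlaps 47 and 112, and the peak ratio of GDC-9545 to DMSO 1.14. In the top 20000 peaks, lost and gained sites were 4 and 0 under GDC-9545 and 0 and 7 under GNE-858, compound-only sites were 0 and 82, both overlaps were 0, and the similarity difference was 0.0550. The gained-to-lost ratios have no useful value there. With absence judged at q of 0.01, the overlap of gained sites was 2109. GDC-9545-only sites then numbered 5869 and GNE-858-only sites 5446, the reverse order of the main counts of 4044 and 4473. At strength percentile 80 or more, the counts were 26 and 1, 1 and 30, and 0 and 235, the ratios 0.0385 (reversed for GDC-9545) and 30, and the overlaps 1 and 0.

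Gene lists that passed for sites lost under GDC-9545 went from 1 to 0 at strong sites and 0 in equal lists, where 0.097 and 0.0171 genes of the called list were expected (0.179 at strong sites with genes matched on strong sites, which also left 0). For sites gained under GDC-9545 they went from 0 to 1 at strong sites with either matching, where the only strong site is that of RAD51, and for GNE-858-only sites from 3 to 1 at strong sites and 0 in equal lists. The 2 lists that no longer passed at strong sites had 0.508 and 0.174 genes expected there, too few to test them, and matching on strong sites left 1 list too (estrogen response, whose ratio went from 6.77 to 3.63, adjusted permutation p = 0.046). In equal lists the 3 had 0.631, 0.190 and 0.0528 expected, again too few to test. Location classes that passed for sites lost under GDC-9545 went from 1 to 2 without matching and to 0 at 2 kb.

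With 1 library left out, the lowest and highest counts were 6840 and 21033 for sites lost under GDC-9545, 10254 and 20772 for gained, 5349 and 18759 for lost under GNE-858, 8780 and 19142 for gained, 7362 and 18502 for GDC-9545-only and 7788 and 18832 for GNE-858-only. The gained-to-lost ratios ran from 0.554 to 3.04 and from 0.514 to 3.58, reversed without either DMSO library (0.554 and 0.817, 0.514 and 0.746). The overlap of lost sites ran from 1572 to 13983, the overlap of gained sites from 1825 to 7573, and the similarity difference from −0.00241 to 0.0429, also negative at −0.000421 without GDC-9545 replicate 2. Strong sites lost under GDC-9545 ran from 35 to 53, gained from 4 to 112, lost under GNE-858 from 1 to 4, gained from 25 to 120, and GDC-9545-only from 0 to 2. Gene lists that passed ran from 0 to 1 for sites lost under GDC-9545 and from 0 to 2 for GNE-858-only sites, and these were not always the lists called in the main analysis. For GNE-858-only sites only histone acetylation and readers passed without GNE-858 replicate 2 (ratio 1.43, adjusted permutation p = 0.0248), only basal and mesenchymal without GDC-9545 replicate 1 (1.83, adjusted permutation p = 0.00207), and estrogen response (1.41) with a depletion of cell cycle genes (0.409) without GDC-9545 replicate 2 (adjusted permutation p = 0.0324 for both). For sites lost under GDC-9545 the list that passed was always estrogen response. Location classes that passed ran from 0 to 3 for sites lost under GDC-9545 and from 1 to 2 for sites lost under GNE-858.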

Other observations

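The test of weak sites below, the strong-site list test and the choice of the chromosome 16 site came after the results were seen.

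Of the 15 fixed genes, 12 had at least 1 site in a changed set, 8 of them a site lost under GDC-9545, 6 a site gained under GDC-9545, 4 a site lost under GNE-858 and 5 a site gained under GNE-858. GREB1 had the most changed sites after ESR1, 9 against 14, with a site counted once in each of the 6 sets that holds it. Near TFAP2C, an AP-2 family gene of luminal cells, a site 34086 bp from the gene (chromosome 20, 56595056 to 56595383) was lost under GDC-9545 at DMSO percentiles of 72.2 and 71.8, and was present in both GNE-858 lists at 21.7 and 49.5. Near MYC, a site 477 bp from the gene (chromosome 8, 127743250 to 127743605) was lost under GDC-9545 at DMSO percentiles of 54.4 and 58.9. Both MYC and TFAP2C sites were also GNE-858-only. A site inside RARA, the retinoic acid receptor alpha gene (chromosome 17, 40347157 to 40347435), was lost under both compounds from weak DMSO percentiles of 28.1 and 16.4.

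A single strong site was lost under both compounds. It lay on chromosome 16 (46399140 to 46400286), 178878 bp from the nearest protein-coding gene, at percentiles 87.6 and 94.7 of the DMSO lists. No peak overlapped it in the 4 treated lists. Its folds in DMSO were 4.70 and 6.14. Sites were not filtered here for regions where reads align poorly, so this single site is only described.

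Sites found in 1 library alone also set DMSO replicate 1 apart. It had 14747 such sites, 6.20% of them within 1 kb of a gene end, against 8189 to 12426 sites and 2.73% to 3.53% in the other libraries.

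The total of changed sites under GNE-858 was not above every other division of the DMSO and GNE-858 libraries. A candidate explanation is that libraries differ in how many weak sites they list. At strength percentile 80 or more the highest count in another division was 1, against 31 for the treatments. These counts had already been seen, and they do not measure how many weak sites each library lists. They therefore cannot decide the explanation. The 3 divisions are too few for a share under 0.05.

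Strong GNE-858-only sites near estrogen response genes may mark places where the compounds differ in GATA3 binding at estrogen receptor targets. The list ratio at strong sites was 3.63 with genes matched on strong sites, on 6 genes (adjusted permutation p = 0.046), and 6.77 with genes matched on all sites, which is inflated by the many strong sites of these genes. In equal lists of 20000 peaks it was 1.59, on 1 gene against 0.631 expected, too few to test. Over all sites the ratio of 1.69 fell to between 0.987 and 1.37 without any 1 of 3 libraries, and the call ended. Receptor binding and gene expression were not analysed here, so whether the receptor is involved was not tested.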
